A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

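RNA of Halobacterium salinarum NRC-1, an archaeon that grows in saturating salt, was measured on 8 spotted arrays that each carried 2 dyes. Per the labels' protocols, cultures in mid-log growth were held for 5 hours in iron sulfate, and channel 1 was labelled with Alexa 532 and channel 2 with Alexa 647. The 4 doses were 2, 4, 6 and 7 mM, with 2 arrays per dose. On 1 array of each dose the iron RNA was in Alexa 532, and on the other it was in Alexa 647. The series' design text speaks of 4 samples, each dye-swapped against a standard control. The 2 arrays of a dose were therefore counted as technical repeats of 1 sample, giving n = 1 sample per dose and n = 4 samples in all. Nothing states how the 4 cultures were related, so p-values rest on the spread between these samples alone. In the moderated fits described below that spread is largely pooled over features. With each feature's own spread alone, 0 features passed either test. The control was present only as the reference channel, so the tests of ratios against 0 leave out the control's own spread.

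The deposited table held 1 log ratio per spot and array, 10752 spots with no missing value, entered here as log10 values. The base is not given in the sources used here. Base 10 was taken because neighbouring spots of the same feature differed by an SD that corresponds to 10.9% on a log10 scale and to 3.17% on a log2 scale, and this remains an assumption. Values are printed in deposited log units, and folds are printed for base 10. Array medians ran from -0.00306 to 0.0523 and SDs from 0.0929 to 0.133. The scanner, background correction, normalization and spot filters of the authors are not given in the sources used here, nor is signal over background, so the number of arrays is the stated limit on precision. Scale, centring and direction of the deposited ratios stay unknown.

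Each feature had 4 spots, a neighbouring pair in each of the 2 print blocks of the slide, called copies here, and the 4 were averaged, leaving 2688 features. The layout held for all 133 genes with a symbol. Of the spots, 532 had 1 gene symbol, 0 had several and 10220 are unnamed here, which leaves 2555 features without a name in the table used. Symbols were matched to the annotation of assembly ASM479960v1, from another strain, which served only for names and for gene neighbours. All 133 matched. Neighbouring spots correlated at r = 0.804 to 0.884 across spots and the 2 copies at r = 0.270 to 0.591.

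Values of arrays with iron in channel 1 were multiplied by 1 and those with iron in channel 2 by -1, and both arrays of a dose were averaged. The result is called the turned ratio. Its positive side means more RNA with iron if the deposited ratio is channel 1 over channel 2, and less if it is the reverse. The labels do not settle which, so sides are given in place of up and down, and all signs would turn together.

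Whether the authors had already turned the swapped arrays is also not settled. The criterion fixed before the data were examined was the correlation across features of the 2 arrays of a dose, to be negative for values not yet turned and positive for values already turned. It came out positive, with r = 0.517, 0.375, 0.333 and 0.715 at 2, 4, 6 and 7 mM. By that criterion the values would be read as already turned. The turned ratio was nevertheless kept as the main reading, a decision made after the values were seen and against that criterion. Its grounds were 20 dose-trend calls on turned ratios against 0 without turning, and a same-sign mean of which 30.2% of the variance followed print order against 7.09% for the turned mean. The turned mean also had heavier tails, with an excess kurtosis of 6.70 against -0.553. The count of trend calls is itself a result reported here, so the calls under the main reading are no evidence for it. At an unadjusted p below 0.05 the trend had more features without turning (253) than with it (182). Other measures went the opposite way or decided nothing, and they stand in the closing section. Counts under the already-turned reading are given beside the main ones. The direction of the ratio is unknown in that reading too, and need not match that of the turned ratio. Same or other side between the readings therefore compares signs of the values only, and the sides could swap.

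Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes) with Benjamini-Hochberg adjustment over 2688 features and a threshold of 0.05. The mean of the 4 turned samples was tested against 0, and a slope per mM was tested over the same samples. SEs are limma's moderated ones, shrunk toward the spread over all features with 19.3 prior degrees of freedom for the mean and 979 for the slope. Over the 27 named genes past the test, they ran from 0.0141 to 0.0268 for the mean, against 0.00383 to 0.0624 from each gene's own samples. Change at each dose was counted without a test, as at least 1 log2 unit (0.301 in log10) on both arrays in the same direction. The planned log2 scale was kept in log10 units for the fits, which alters no p-value. Of 20 gene lists fixed before the data were examined, 8 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, against the 133 named genes as background, with an estimated correlation and fry as alternatives. Figures were drawn with matplotlib 3.10.9.

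Genes named in the text were, by a rule fixed before the data were examined, the 12 with the largest mean in each direction among those past the test with 1 sign at all 4 doses, the 10 largest slopes in each direction, up to 4 members per list with the smallest p, and 20 genes to be named always, of which 2 were measured. Because most features are unnamed here, the rule was applied to the named genes, with at most 2 unnamed features per direction, identified by their first spot number. That restriction was decided after the values were seen.

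The fits were tested on simulated data with 200 changed features among 2688. For the mean over all doses, 0% were recovered at a change of 0.05, 93% at 0.1 with 11 false calls and 99.5% at 0.2 with 14 false calls. For the dose trend, 0% were recovered at a total change of 0.05 or of 0.1 over the dose range and 71.5% at 0.2, with 3 false calls. Simulated noise was normal and independent between arrays, and the dye bias was equal on all arrays, so that turning cancelled it. Print-block offsets, print-order trends and a deviating control were not simulated. These shares hold for that setting alone, since in the data genes with means as small as 0.0457 (carA) passed. Alternatives covered leaving out each sample, single dye orientations, centring, scaling, the summary over spots, variance shrinkage, dye and block terms, dose scale and thresholds. Alternatives added after the data were seen were the already-turned reading, removal of print-order trends by a running median over 65 features, centring of each print block, 236 exact zeros taken as missing, each spot copy alone, log2 as the base and all features as list background.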

Results

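The series recorded how RNA levels in Halobacterium NRC-1 differed from a control after iron sulfate at 2, 4, 6 or 7 mM, with 1 sample per dose measured on 2 dye-swapped arrays. All 8 arrays gave values for 2688 features, of which 133 carried a gene symbol. Turned ratios are given in deposited log units, with the base taken as 10. Sides are called positive and negative because the labels do not settle which of them is higher with iron. A 2nd limit applies to every value: the correlation of swapped arrays before turning was positive, which by the criterion set in advance would mean that the values had already been turned. The results depended on this: of the 27 named genes past the test on turned ratios, 1 (arcC) passed on the same side in the already-turned reading, 9 passed on the other side and 17 did not pass. Here and below, sides of the readings are compared by sign alone. Direction is unknown in both, so same and other side could swap.

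Over all 4 doses, phoU, which encodes a regulator of phosphate uptake, had the largest mean of the named genes, 0.162 ± 0.0268 (limma's moderated SE, n = 4 samples), 1.45-fold if the base is 10. All SEs given with ± are moderated, which means shrunk toward the spread over all features; the SE of phoU from its own 4 samples was 0.0624. At the opposite side, glnA, which encodes glutamine synthetase, had a mean of -0.0912 ± 0.0147, or 1.23-fold. Turned ratios of both genes had their side on all 8 arrays, with limma adjusted p of 2.38e-04 and 1.98e-04. On the first spot copy alone the call on glnA was lost (adjusted p = 0.113). The means of phoU and glnA in the already-turned reading were 0.0276 (adjusted p = 0.127) and -0.0106 (adjusted p = 0.570). Of the 133 named genes 27 passed the test, 14 on the positive and 13 on the negative side, and 31 passed when adjusted over the named genes alone.

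On the positive side thiC had a mean of 0.108 ± 0.0154 (adjusted p = 4.86e-05) and thiD 0.0822 ± 0.0155; both act in thiamine synthesis. Also on this side were secY, for the channel subunit of the protein export machinery, at 0.0860 ± 0.0146, and the ribosomal protein genes rpmC at 0.0854 ± 0.0160 and rpl12p at 0.0484 ± 0.0142. The glucosamine phosphate synthase gene glmS had a mean of 0.0750 ± 0.0148. In central metabolism citZ (citrate synthase) had 0.0643, eno (enolase) 0.0601, carB (carbamoyl phosphate synthase) 0.0564 and lpdA (dihydrolipoamide dehydrogenase) 0.0533. The gene dpsA, for a ferritin-like protein that binds DNA and stores iron, had a mean of 0.0722 ± 0.0156 (adjusted p = 0.00289). Its turned ratio was positive at all 4 doses but on only 4 of 8 arrays, since all arrays carried a negative deposited value. On the Alexa 532 arrays alone its mean was -0.0729 (adjusted p = 0.0190). All arrays of lpdA likewise carried a negative deposited value, so that its turned ratio was positive on 4 of 8. In the already-turned reading dpsA (-0.145, adjusted p = 5.36e-04), secY (-0.0826, adjusted p = 0.00647), eno (-0.0740, adjusted p = 0.00429), lpdA (-0.0603, adjusted p = 0.00819) and carB (-0.0540, adjusted p = 0.0134) passed on the negative side. The means of thiC (-0.0467), thiD (-0.0345), citZ (-0.0163) and rpl12p (-0.0230) also took the other sign there without passing.

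On the negative side were purF at -0.0879 ± 0.0157 (adjusted p = 5.23e-04) and purL at -0.0817 ± 0.0150 (adjusted p = 6.44e-04), both of purine synthesis and each on all 8 arrays. They were joined by cheR, a methyltransferase of chemoreceptors, at -0.0695 ± 0.0147, panB of pantothenate synthesis at -0.0662, cobN of cobalamin synthesis at -0.0621 and the transducer gene htr4 at -0.0562. Smaller means were those of arcC (carbamate kinase, -0.0535), hisS (histidyl-tRNA synthetase, -0.0513), psmB (a proteasome subunit, -0.0486) and moaA of molybdenum cofactor synthesis (-0.0479). The arginine deiminase gene arcA, 1 of the 2 measured genes that were to be named always, had 0.0118 ± 0.0145 and did not pass (adjusted p = 0.668). It did pass on Alexa 532 arrays alone at -0.0668 (adjusted p = 0.0191), on Alexa 647 arrays alone at 0.0904 (adjusted p = 0.00852) and in the already-turned reading at -0.0786 (adjusted p = 0.00303). In that reading hemA (0.120, adjusted p = 0.00195), panB (0.0958, adjusted p = 0.00220), htr4 (0.0767, adjusted p = 0.00282) and srp19 (0.0695, adjusted p = 0.0114) passed on the positive side, and purF (0.0233), cheR (0.0185), moaA (0.0166) and hisS (0.00529) had the other sign without passing.

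**Figure D1:**
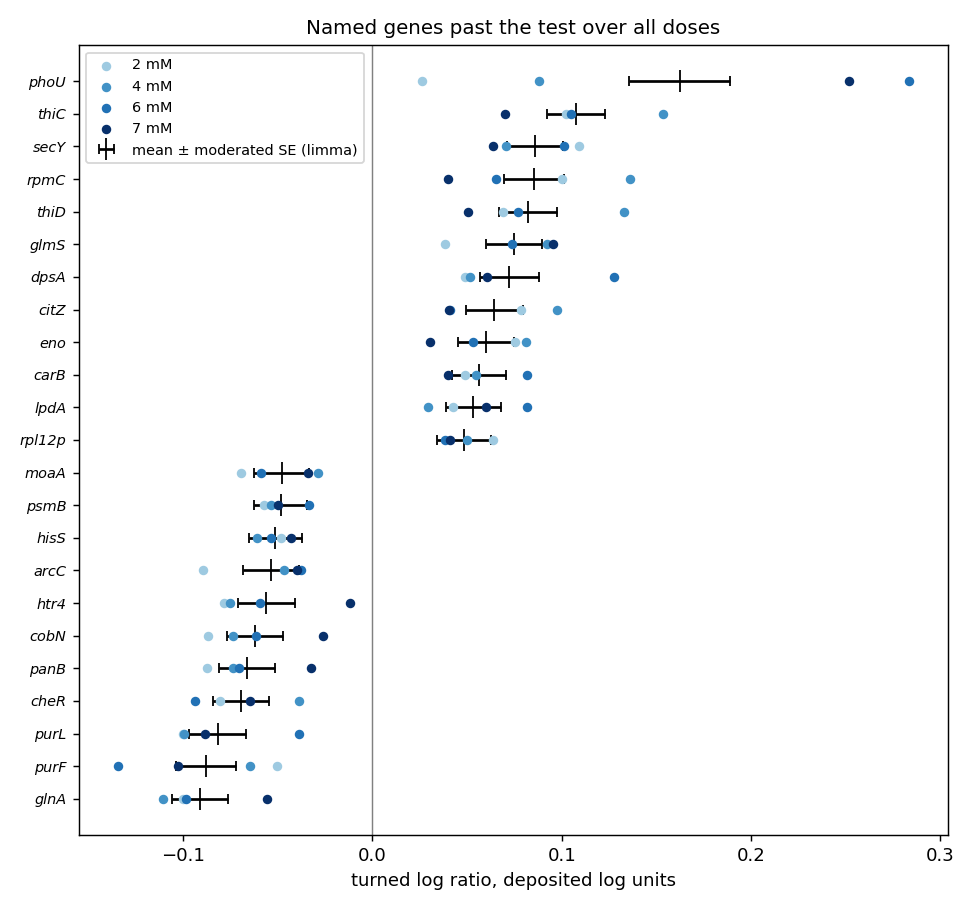
Turned log ratios (horizontal axis, deposited log units) of named genes past the test with 1 sign at all 4 doses, up to 12 per side. Points are doses and bars the mean of 4 samples ± limma's moderated SE; phoU has the widest spread between doses, from 0.0261 at 2 mM to 0.283 at 6 mM.

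Among all 2688 features 342 passed, 188 positive and 154 negative, with a median size of 0.0614, and 682 had an unadjusted p below 0.05. On turned ratios the largest positive mean was 0.167 at the unnamed feature of spot 1407, followed by that of phoU. The largest negative means were those of the unnamed features at spots 4291 (-0.280) and 4299 (-0.229). Their turned ratios at 2, 4, 6 and 7 mM were alike, -0.308, -0.353, -0.268 and -0.192 at spot 4291 and -0.285, -0.278, -0.204 and -0.150 at spot 4299. They lie 8 spots apart, a spacing taken up in the closing section, and an effect of position was not tested for them. The features at spots 1407, 4291 and 4299 had, in the already-turned reading, -0.0410, 0.0674 and 0.0197, so that each lay on the other side. If the values had already been turned, 1548 features passed, 1165 positive and 383 negative, among them 68 named genes. In that reading the median over features was 0.0183, 0.0188, 0.0348 and 0.0546 at 2, 4, 6 and 7 mM. Array offsets may therefore account for part of the count and of its positive excess, which was not tested. Compared by sign alone, 58 of the 342 features passed on the same side in the already-turned reading and 128 on the other. Without the 2 mM sample 192 passed, without the 6 mM sample 187, and with no variance shrinkage 0. With robust shrinkage phoU missed the threshold (adjusted p = 0.159).

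Taken on 1 dye orientation alone, 6 of the 27 named genes passed on their side on each: phoU, glmS, thiC, glnA, purF and purL. The mean on Alexa 532 arrays is the turned mean plus the already-turned mean, and on Alexa 647 arrays the turned mean minus it. A sign changed on 1 dye therefore restates the size of the already-turned mean. These counts are no check separate from that reading. On Alexa 532 arrays alone 10 kept their call, 10 kept their sign without passing and 7 took the other sign. Of those that kept their sign, secY had 0.00344 (adjusted p = 0.926) and carB 0.00241 (adjusted p = 0.937), against 0.169 and 0.110 on Alexa 647 arrays alone. Also short of the threshold on Alexa 532 arrays were carA (adjusted p = 0.513), gyrA (0.378), rpl12p (0.307), moaA (0.204), thiD (0.0810), hisS (0.0784), cheR (0.0611) and citZ (0.0581). On Alexa 647 arrays alone 22 kept their call, arcC took the other sign, and psmB (adjusted p = 0.561), rpmC (0.187), cobN (0.109) and hisS (0.0528) fell short.

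With 1 sample left out, 3 samples remained and several named genes missed the threshold, while their means stayed at 0.666 to 1.21 times the full mean (median 0.928). Of the 27 calls 13 were lost without the 2 mM sample, 8 without 4 mM, 12 without 6 mM and 1 without 7 mM, and 12 held whichever sample was left out. The call on gyrA was lost in all 4 cases (adjusted p from 0.0576 to 0.240). Those on psmB (0.0618 to 0.147), hisS (0.0530 to 0.0876), hemA (0.0547 to 0.137), htr4 (0.0564 to 0.126), rpl12p (0.0564 to 0.178), carA and srp19 were each lost in 3. The call on lpdA was lost without 2 mM (0.0590) and without 6 mM (0.158), and so was that on moaA (0.218 and 0.157). Without 2 mM arcC (0.201), cobN (0.0788) and eno (0.0717) missed the threshold, and without 6 mM carB (0.111) and dpsA (0.0647) did. On the first spot copy alone 10 of the 27 calls were lost, among them glnA (limma adjusted p = 0.113), panB (0.178) and cheR (0.257). On the second copy alone 14 were lost, among them thiD (0.137), citZ (0.224) and rpmC (0.151). Over all features 239 passed on the first copy and 224 on the second, of which 77 were shared, each with the same sign.

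Only phoU among the named genes had a called dose trend, with a slope of 0.0531 ± 0.00803 per mM (limma's moderated SE, adjusted p = 1.68e-07, n = 4 samples). With 979 prior degrees of freedom that SE was almost wholly the spread pooled over features; from the 4 samples of phoU alone it was 0.0133. Its turned ratio was 0.0261, 0.0880, 0.283 and 0.252 at 2, 4, 6 and 7 mM. The first spot copy gave 0.0345, 0.105, 0.409 and 0.300 and the second 0.0177, 0.0707, 0.158 and 0.203. On arrays with iron in Alexa 532 the deposited value of phoU went from 0.0400 at 2 mM to 0.281 at 7 mM, and on swapped arrays from -0.0122 to -0.222. Across all features 20 had a called slope, 11 positive and 9 negative, and 182 had an unadjusted p below 0.05. Unnamed features with large slopes were those at spots 4877 (0.0350) and 1803 (0.0339) on the positive side and at spots 4245 (-0.0514) and 1985 (-0.0492) on the negative side. Their slopes in the already-turned reading were 0.0179, -0.00812, 0.00653 and 0.00788, and none passed. At spot 4877 the deposited values at 7 mM were 0.585 on the Alexa 532 array and 0.152 on the Alexa 647 array, of 1 sign. With print-order trends removed its call was lost (limma adjusted p = 0.208), while those at spots 1803, 4245 and 1985 held. In both tests 10 features passed.

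The call on phoU was lost in several settings with a slope of similar size: without the 2 mM sample (slope 0.0607, adjusted p = 0.451), on Alexa 532 arrays alone (0.0545, adjusted p = 0.838), on Alexa 647 arrays alone (0.0516, adjusted p = 0.463) and with no variance shrinkage (0.0531, adjusted p = 0.938). It was also lost on the first copy (0.0686, adjusted p = 0.229) and on the second copy (0.0375, adjusted p = 0.192). Across all features the slopes on the 2 copies correlated at r = 0.287. In the already-turned reading the slope of phoU itself was near 0 (0.00143, adjusted p = 0.961). Leaving out samples gave 0 trend calls without 2 mM, 6 without 4 mM, 10 without 6 mM and 7 without 7 mM, and the already-turned reading gave 0, with 253 features at an unadjusted p below 0.05.

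**Figure D2:**
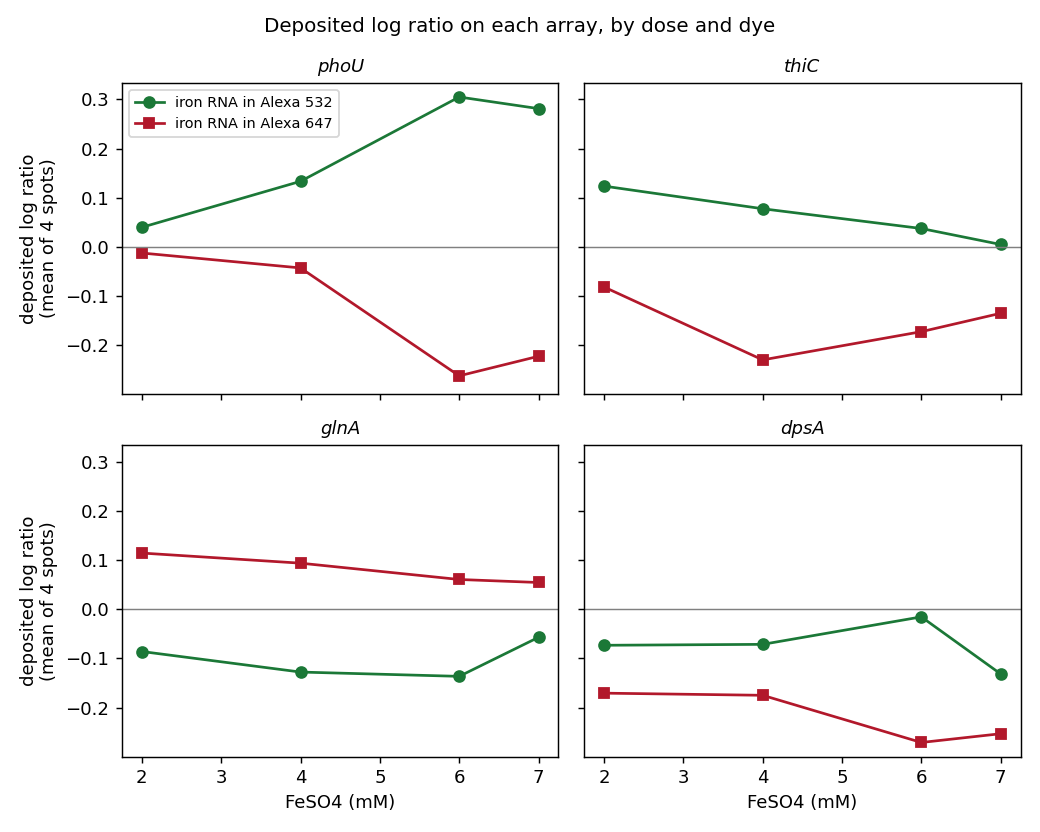
Deposited log ratio (vertical axis, mean of 4 spots) against iron sulfate dose in mM for phoU, thiC, glnA and dpsA, with 1 line per dye orientation and 1 array per point. Lines of phoU part with dose, from 0.0400 and -0.0122 at 2 mM to 0.281 and -0.222 at 7 mM, while both lines of dpsA stay below 0.

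At single doses few features reached 1 log2 unit on both arrays, if the base is 10. The feature at spot 4291 did so on the negative side at 2 mM (-0.308) and at 4 mM (-0.353), and 0 features did at 6 or 7 mM. At 2 mM it no longer did so with centring, scaling, print-order removal or print-block centring. In the already-turned reading it did so at neither dose. At 1.5-fold, 3 features passed at 2 mM, 6 at 4 mM, 5 at 6 mM and 3 at 7 mM. On turned ratios the largest positive means at 6 and 7 mM were those of phoU, 0.283 and 0.252. In the already-turned reading phoU had 0.0215 and 0.0296 there, against largest values of 0.219 and 0.368 at unnamed features. These counts have no replicate check, because each dose had 1 sample.

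Of the 8 gene lists with at least 3 measured members, camera called 0 for the mean over all doses and 0 for the dose trend. Unadjusted p was below 0.05 for 1 list in each, and fry, run beside camera, gave a smallest adjusted p of 0.162 for the mean and 0.742 for the trend. The chaperone and proteasome list had all 5 members on the negative side and an adjusted p of 0.0569, or an adjusted p of 0.655 with an estimated correlation. Of its members psmB passed, 2 passed when adjusted over the list alone, and dnaK had -0.0379, psmA -0.0331 and pan1 -0.0278. In the already-turned reading psmA had 0.113 and pan1 0.0896. On Alexa 532 arrays alone psmA had 0.0797 and pan1 0.0617, and on Alexa 647 arrays alone dnaJ had 0.0110. In heme and cobalamin synthesis cobN and hemA (-0.0631, negative at 3 of 4 doses) passed on the negative side, 2 of 5 members, and cbiG had 0.0247 and hemL -0.0163 (camera adjusted p = 0.322). The call on hemA was lost with a dye term and dose as a random block (limma adjusted p = 0.0538). In anaerobic respiration and arginine fermentation arcC and moaA passed, 2 of 4 members, while moaC had 0.0215 (camera on the list, adjusted p = 0.322).

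In motility and chemotaxis cheR and htr4 passed on the negative side, 2 of 9 members, and htr6 had 0.0394 and cheY -0.0362 (camera adjusted p = 0.310). Adjusted over the list alone, 1 positive and 3 negative members passed. The sensory and bacterio-opsin list had 0 of 6 members past the test, with sop1 at 0.0402, htr1 at 0.0362, bat at 0.0283 and sop2 at 0.0270 (camera on the list, adjusted p = 0.264). In DNA repair and replication gyrA passed at 0.0464, 1 of 8 members, and uvrB had 0.0347, gyrB 0.0289 and uvrA -0.0274 (camera on the list, adjusted p = 0.322). In the citric acid cycle citZ passed, 1 of 6 members, and sucC had -0.0242, sdhC -0.0171 and mdh 0.0118 (camera on the list, adjusted p = 0.810). In amino acid synthesis glnA passed, 1 of 15 members, and gdhA1 had 0.0420, argH -0.0407 and hisA 0.0294 (camera on the list, adjusted p = 0.758). The median of that list was 0.00595 and its mean -0.00165. Adjusted over the list alone, the counts were 2 negative in heme and cobalamin synthesis, 2 negative in the anaerobic list, 1 positive in each of DNA repair and the citric acid cycle, 1 negative in amino acid synthesis and 0 in the opsin list.

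Lists too small to test held dpsA and msrA (0.00886) for iron storage and oxidative stress, fer2 (0.00123) and sdhC for iron-sulfur proteins, nuoL (0.0211) for the respiratory chain, cbiQ (0.00633) for metal transport, rpl12p for ribosomal proteins and phoU for phosphate transport. The symbol pattern of the ribosomal list missed rpmC. Iron uptake, metal-dependent regulators, ATP synthase, gas vesicles, general transcription factors and insertion sequences had 0 named members and were not analysed here.

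**Figure D3:**
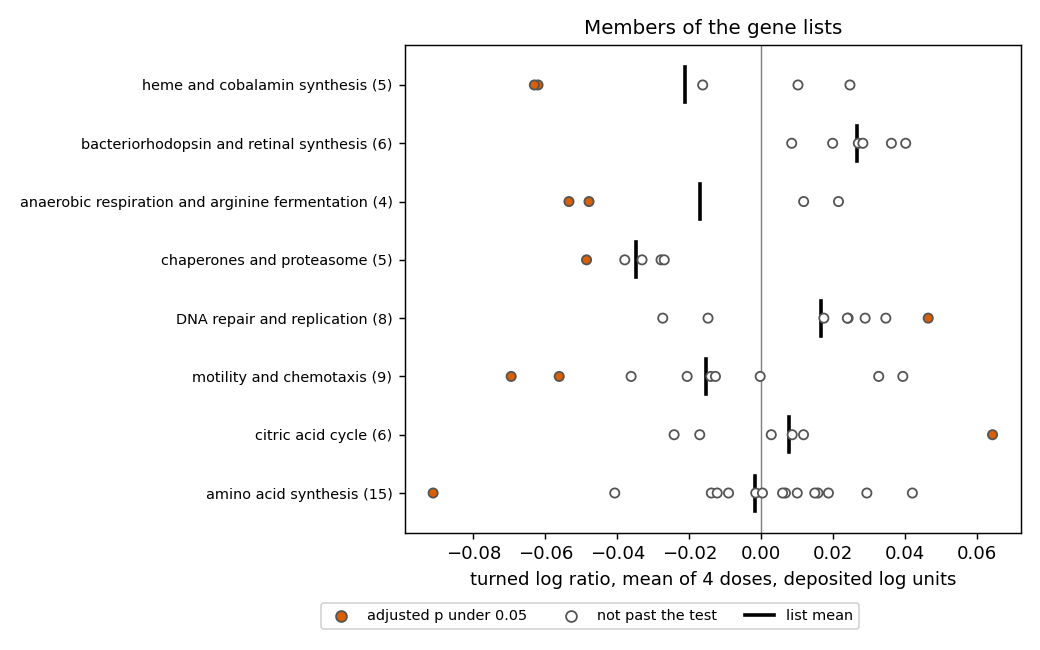
Mean turned log ratio over 4 doses (horizontal axis, deposited log units) of each member of the 8 tested lists, with the number of measured members in brackets; filled points passed the gene test and bars mark list means. All 5 chaperone and proteasome genes lie below 0, from -0.0270 to -0.0486, though psmA has 0.113 and pan1 0.0896 in the already-turned reading.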

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

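Apart from the planned tests of the mean and the slope, whose calls are taken up here, all tests in this part were chosen after the results were seen. Some features the text names differed between doses by the test of the slope: phoU (0.0531 per mM) and the unnamed features at spots 4877 (0.0350), 1803 (0.0339), 4245 (-0.0514) and 1985 (-0.0492). These slopes in the already-turned reading were 0.00143, 0.0179, -0.00812, 0.00653 and 0.00788, the last 3 with the other sign.

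The first pattern is that features such as phoU moved with dose in opposite directions on swapped arrays. If the deposited values were already turned, opposite signs could come from dye bias that changes with dose. Without turning 0 trend calls were made, against 20 after turning, but at an unadjusted p below 0.05 there were 253 features against 182. The main reading was chosen partly on these calls, so they do not decide between the readings. Among the 20 features with the largest slope on 1 set of arrays, most had opposite slopes on the other set: 13 when chosen on Alexa 532 arrays and 15 on Alexa 647 arrays with print-order trends removed, and 15 and 18 with each array centred. Among the top 100 the counts were 51, 55, 45 and 42, near the 47.5% (trends removed) and 42.9% (arrays centred) of all features. Of 24 possible pairings of swapped arrays, the true one included, 21 had a sum of products as low as the true one. Values not yet turned would put it among the lowest if dye bias was equal at all doses. With a dye term fitted and dose as a random block, turned arrays of a dose had a correlation of -0.189 for the mean. For the trend it was -0.269. Repeats of 1 sample should vary together if turning was right and dye bias was equal at all doses, so under that condition these values go against the main reading. The dye term was constant over doses, so a dye bias that changed with dose could also give negative values. Similarity of neighbouring genes was stronger without turning (one-sided permutation p = 0.0008, against 0.0977 after turning), and with print-order trends removed p was 0.0119 against 0.121. Pairs of 1 sign were 13 of 18 without turning and 14 after. Both readings stay open, and an iron effect on phoU is a hypothesis that holds only if the values had not been turned.

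The second pattern is the dose trends themselves, which could come from position on the slide. With print-order trends removed 5 of the 20 calls remained, phoU among them (adjusted p = 0.00723), and in all 5 the slopes on both spot copies had 1 sign and differed by less than 2 times, which argues against an effect local to 1 copy as their whole cause. The copies of phoU differed most at 6 mM, with 0.409 and 0.158, so part of its size there may be local to the first copy. For another 5 the slope came mainly from 1 copy, the second in each, and their first spots ran from 4813 to 5187. Their copy slopes differed by at least 2.43 median absolute deviations, which leaves an effect local to 1 copy open. The shared copy and stretch go with such an effect, which was not tested separately. Within that stretch the called feature at spot 4877 had similar slopes on both copies (0.0324 and 0.0376). The 5 features had slopes of similar size after removal (ratios from 0.859 to 1.08, median slope 0.0302 before and 0.0314 after), which argues against a smooth print-order trend as their whole cause.

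For the other 10 the ratios of slopes after to before removal ran from 0.818 to 1.10. The median slope went from 0.0328 (median SE 0.00802) to 0.0289 (median SE 0.00709), which argues against a smooth print-order trend as their whole cause. Every unadjusted limma p after removal was 0.0163 or below. These features were chosen by their slopes on the same arrays, so that p is no separate test. After removal the prior degrees of freedom of the limma fit fell from 979 to 8.87, so that slopes with a similar ratio to their SE had larger p. A position effect too narrow for the running median and shared by both copies could remain: 2 pairs of the 20 features lay 8 spots apart, against 0.146 on average in 10000 random draws (permutation p = 0.0088), but that distance was picked from these same features. The features at spots 4291 and 4299, with the largest negative means over all doses, also lie 8 spots apart, so the same doubt applies to them. Dose and culture are 1 to 1 here, so culture differences also stay open and untested.

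The third pattern is that 332 features passed over all doses without a called trend. Because a single control served all arrays, a deviation of that control RNA would give such features too, and it cannot be told apart from an iron effect of equal size at each dose. Calls also split by spot copy: 82.0% of first-copy calls were positive and 21.9% of second-copy calls. First-copy values had a median of 0.0193 and second-copy values one of -0.0102. Centring each print block of each array brought the shares to 53.0% and 40.6%, but centring by itself evens such shares, so the cause of the split stays open.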

How the results depend on the processing

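Alternatives added after the data were seen were the already-turned reading, print-order removal, print-block centring, exact zeros as missing, single copies, log2 as the base and all features as list background. The number of arrays limits precision, since signal over background was not used here. The cause of each difference was not tested. Single copies and left-out samples carry fewer values, and so do single dye orientations, where calls over all doses nevertheless rose. Single-dye means are the turned mean plus or minus the already-turned mean, so they are no check apart from that reading. The planned filter on values on every array and the lists by symbols alone gave the main values, since no value was missing and the reference tables used give no product names. No paired analysis was possible because each dose had 1 sample.

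For the mean over all doses, 342 calls became 187 to 356 when 1 sample was left out, 1313 on Alexa 532 arrays alone (1040 positive), 1271 on Alexa 647 arrays alone (343 positive), 1548 if already turned, 224 on the second copy alone, and 0 without shrinkage or with at least 1 log2 unit required. The count was 302 to 438 under the other settings except the first copy alone (239, with 196 positive and 43 negative). Print-order removal kept 302 of the 342. The single-dye and already-turned counts also keep array offsets that averaging of turned arrays partly cancels.

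The 20 trend calls became 0 to 10 when 1 sample was left out, 0 on either dye alone, without shrinkage, if already turned or on either copy alone, 8 with centring, 4 with scaling, 5 with print-order removal, 8 with the median over spots, 5 with a dye term and dose as a random block, 12 with disagreeing features left out, 5 on log2 dose and 12 with print-block centring. They were 20 with robust shrinkage, 18 on dose ranks and 15 with zeros missing.

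For single doses at 2, 4, 6 and 7 mM, counts were 3, 3, 3 and 28 on Alexa 532 arrays alone, 5, 4, 5 and 12 on Alexa 647 arrays alone, and 3, 6, 5 and 3 at 1.5-fold. The 2 mM count became 0 with centring, scaling, print-order removal or print-block centring, and the 2 mM and 4 mM counts became 0 if already turned or with log2 as the base.

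Of the lists 1 was called for the mean, chaperones and proteasome, without the 7 mM sample (adjusted p = 0.0153), with scaling (0.0461), on the first copy (0.0155) and against all features (0.0284). With an estimated correlation these 4 became 0.672, 0.659, 0.500 and 0.590. Leaving out a sample gave 0 to 1 lists. For the trend 1 was called, the anaerobic list, on Alexa 647 arrays alone (0.00136) and with print-order removal (0.0202), or 0.473 and 0.712 with an estimated correlation.

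Signs of the mean were followed for 28 named genes, the 27 past the test and arcA. In the already-turned reading the direction of the values is unknown, so same and other sign could swap there. Of all 133 named genes, 77 took the other sign if already turned, 54 on Alexa 532 arrays alone and 38 on Alexa 647 arrays alone. If already turned, 20 of the 28 did: thiC -0.0467, secY -0.0826, thiD -0.0345, dpsA -0.145, citZ -0.0163, eno -0.0740, carB -0.0540, lpdA -0.0603, rpl12p -0.0230, gyrA -0.0226, carA -0.0282, arcA -0.0786, moaA 0.0166, hisS 0.00529, htr4 0.0767, hemA 0.120, srp19 0.0695, panB 0.0958, cheR 0.0185 and purF 0.0233. Of these, 10 passed on the other side: dpsA, secY, eno, carB, lpdA, arcA, htr4, hemA, srp19 and panB. On Alexa 532 arrays alone 8 of the 28 did: dpsA -0.0729, eno -0.0139, lpdA -0.00704, arcA -0.0668, htr4 0.0205, hemA 0.0566, srp19 0.00410 and panB 0.0296, of which dpsA and arcA passed. On Alexa 647 arrays alone 1 of the 28 did, arcC at 0.0120. Of 25 further genes from the lists, 18, 14 and 4 did in these 3 settings.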

Other observations

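Apart from the planned gene test over all doses, all groups and tests in this part were chosen after the values were seen. In thiamine synthesis thiC and thiD passed on the positive side and thiL had -0.00857, a list result of adjusted p = 0.229 by camera. In purine synthesis purF and purL passed on the negative side, 2 of 7 measured genes, while purB had 0.00143 (camera on the group, adjusted p = 0.294). In pyrimidine synthesis carA (0.0457) and carB passed on the positive side, 2 of 5 genes (camera on the group, adjusted p = 0.639). Of 12 aminoacyl-tRNA synthetase genes only hisS passed the gene test over all doses (camera on the group, adjusted p = 0.994). In glycolysis and gluconeogenesis eno passed, 1 of 3 genes (camera on the group, adjusted p = 0.477). In histidine degradation 0 of 3 did (camera on the group, adjusted p = 0.994). With an estimated correlation the adjusted p of these 6 groups ran from 0.748 to 0.996.

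One hypothesis was that neighbouring genes, which may share a transcript, have similar turned means. Over 18 pairs of named neighbours less than 100 bp apart, r across pairs was 0.567 and 14 pairs had 1 sign, among them carB and carA, sop1 and htr1, and gyrB and gyrA. A one-sided permutation test gave p = 0.0977 (Benjamini-Hochberg 0.121 over 5 versions), which misses the threshold. For the mean taken without turning the permutation test gave p = 0.0008 (Benjamini-Hochberg 0.00400), with 13 pairs of 1 sign. With print-order trends removed, 11 pairs had 1 sign after turning (permutation p = 0.121) and 16 without turning (permutation p = 0.0119, Benjamini-Hochberg 0.0298).

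The gene srp19, of the signal recognition particle, passed over all doses at -0.0654 but was positive at 7 mM (0.00922).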
